A study of Homo sapiens with 46 samples.

How the data were processed

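RNA from 46 human lung samples was labelled with Cy3 and hybridised to Agilent whole human genome arrays with 4 arrays per slide, 1 sample per array, per the labels' protocols. The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 9.5.1.1 per the file headers. Its intensity columns hold the processed signal, the mean signal and the local background, on a linear scale, and probe coordinates in the files are on hg18. The deposited series matrix holds the intensity values of the processed signal of the same arrays, matched on the spot number. Its column medians run from 62.6 to 299, it is neither logged nor centred, and it equals the scanner files exactly for 31 arrays and within a relative difference of 0.00499 for the other 15 arrays, whose scanner files are rounded to 3 digits.

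Control spots and spots marked by the scanner software as outliers were left out, and the 10 spots of 264 repeated probes were averaged. This left 41000 probes. The log2 of the processed signal minus the log2 of each array's 75th percentile was the main value. Through the reference table, 23680 probes were named by accession, 2802 by symbol and 1128 by a synonym of a single gene, and 13390 were not named and not tested. Probes of Y-linked genes and XIST (133) were left out. A probe had to be well above background on at least 8 arrays, the size of the smallest group, which 33760 did. Per gene the probe with the highest mean was used, which gave 16070 genes, of which 6236 had several probes. Of the genes called, 2 in UIP vs control, 3 in AEx vs control and 0 in AEx vs UIP had other probes called in the opposite direction.

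The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (group means, contrasts, eBayes with trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, two-sided. Gene lists (33) were tested with camera with an estimated correlation, adjusted over the lists of a comparison, for lists with at least 5 genes, on the genes with a value on every array, which leaves out 254. A probe not well above background on any array of a group gives only a bound, the mean of the brighter group against, per array, the higher of the lowest signal well above background and the probe's own. Genes named in the text are MMP1 and MMP7, per comparison the 10 largest rises and the 10 largest falls past the threshold, leaving out placeholder names, up to 4 members past the threshold of each list described, or the 2 with the highest mean where none passed, and CCNA2 and DEFA4 in the AEx comparisons. A gene that this rule takes is not reported here. The rule, the lists, the main test and the alternatives were fixed before the data were examined, except where stated.

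The code was tested on simulated data with 16070 genes and the real group sizes. For a true log2 fold change of 1, 70% of changed genes were recovered for UIP vs control, 54% for AEx vs control and 58% for AEx vs UIP. For a change of 2 these were 98%, 86% and 92%. Of 215, 180 and 184 genes called in UIP vs control, AEx vs control and AEx vs UIP, 17, 8 and 8 were unchanged. The simulated genes varied independently of each other, unlike the real ones, so the rate of false calls in the real data may differ.

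The files give 16 slides and 4 scan days. Scan day 1 held 1 UIP array, day 2 held 4 arrays of each group, day 3 held 4 AEx, 5 control and 4 UIP arrays, and day 4 held 6 control and 14 UIP arrays. Both were tested as blocks, and each day with over 1 group was also fitted alone. Control arrays were all at slide position 4, AEx arrays all at position 1 and UIP arrays at positions 1 (5), 2 (12) and 3 (6). Within groups the median correlation between arrays was 0.936 for control, 0.934 for UIP and 0.934 for AEx (Pearson's r across probes), the lowest for any pair was 0.806, 0.819 and 0.884 in that order, and the highest for any pair within a group was 0.976. Alternatives covered normalization, background correction, the filter, the probe rule, the series matrix values, the samples in the fit, eBayes without trend, array weights, blocks and leaving out each array. Chosen after seeing the data were fits within a scan day, fits of scan days 2 and 3 alone, unnamed probes as features, a fit without the 2 arrays that correlated least with their group, and gene families chosen later with scan day or slide as a block.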

Results

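Gene expression was measured in 46 human lung tissue samples with single-colour Agilent whole human genome arrays, 1 array per sample. The control group held 15 samples of lung with normal histology from the margins of lung cancer resections. The UIP group held 23 samples from biopsies or explanted lungs of patients with idiopathic pulmonary fibrosis, a scarring disease of the lung whose microscopic pattern is called usual interstitial pneumonia. The AEx group held 8 samples from patients with idiopathic pulmonary fibrosis whose pathology pointed to an acute exacerbation, a sudden worsening of the disease. The labels call the samples biological replicates and do not state for the control and UIP samples that each came from a different person, so the p-values measure the spread between these samples. The 75th percentile of the processed intensity lay between 361 and 1467 over the arrays, and 59.5% to 85.4% of the probes of an array were well above background. The number of arrays limits the precision, with a median standard error of a log2 fold change of 0.209 for UIP vs control, 0.275 for AEx vs control and 0.258 for AEx vs UIP. Levels below are log2 intensities relative to the array's 75th percentile, and each is given as the mean ± SD over arrays.

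The first comparison asked which genes differ between fibrotic and control lung, with attention to MMP1 and MMP7, which the series' title names as possible blood markers of the disease. MMP1, an interstitial collagenase, and MMP7, also called matrilysin, were both higher in UIP than in control lung. The MMP1 level was 2.01 ± 2.12 (SD, n = 23) in UIP and -2.58 ± 2.70 (SD, n = 15) in control, a log2 fold change of 4.58 ± 0.71 (SE) with a limma adjusted p of 2.25e-05. The MMP7 level was 3.50 ± 1.36 (SD, n = 23) in UIP and 0.40 ± 1.80 (SD, n = 15) in control, a log2 fold change of 3.10 ± 0.53 (SE) with a limma adjusted p of 8.61e-05. With normexp background correction the MMP1 log2 fold change was 3.42 after 75th percentile scaling and 3.44 after quantile normalization, and both passed. All 23 UIP arrays lay above the control mean for MMP1 and also for MMP7. A two-sided permutation test with 100000 resamples gave p = 1e-05 for each gene, the smallest it can give. In hg18 coordinates the MMP1 probe lies on chromosome 11 from 102165907 to 102165966 and the MMP7 probe on chromosome 11 from 101899239 to 101899298, both on the minus strand. The log2 fold changes of MMP1 and MMP7 were 4.74 and 3.11 with scan day as a block, and with slide as a block they were 4.81 and 3.12. Within scan days 2, 3 and 4 the MMP1 log2 fold change was 8.12, 3.07 and 4.07, and the limma adjusted p on scan day 3 was 0.578. For MMP7 the values were 4.37, 3.07 and 2.55, with limma adjusted p of 0.0754 on scan day 2 and 0.557 on scan day 3, so that the call ended on those days.

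**Figure D1:**
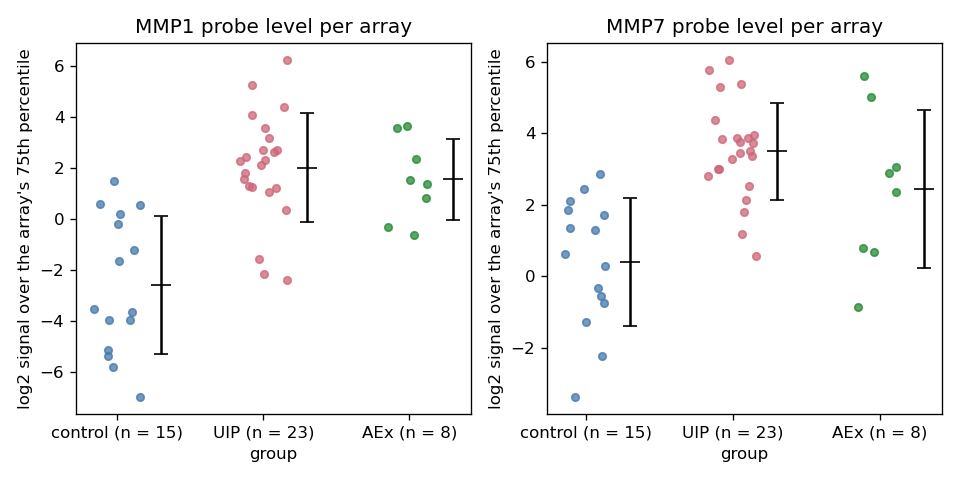
Level of the MMP1 probe (left) and the MMP7 probe (right) on each array, as log2 intensity over the array's 75th percentile, by group. Points are arrays and the black marks are the mean ± SD; all 23 UIP arrays lie above the control mean in both panels.

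Among the largest rises in UIP were those of COMP, COL17A1 and SPP1, and among the largest falls those of ITLN2 and RTKN2. COMP, a cartilage and tendon matrix protein, rose by a log2 fold change of 4.07 ± 0.36 (SE) with a limma adjusted p of 4.25e-11. COL17A1, a hemidesmosome collagen of basal epithelial cells, rose by 4.48 ± 0.51, and the basal keratin KRT5 rose by 3.57 ± 0.77. SPP1, the matrix protein osteopontin, rose by 3.66 ± 0.53, with all 23 UIP arrays above the control mean. MMP10 and BPIFB1 rose by 3.48 and 3.44. KRT6C rose by 3.93, and its probe may also detect the near-identical KRT6A and KRT6B. IGFL2 was not well above background on any control array, and its level was at least 3.8-fold higher in UIP. The intelectin ITLN2, the type 1 cell gene RTKN2 and the serotonin transporter SLC6A4 had log2 fold changes of -4.12, -3.10 and -3.05. SERTM1, HTR3C, CA4, SLCO1A2, SOSTDC1, NECAB1 and BTNL3 had log2 fold changes between -2.97 and -2.42, and the call of BTNL3 ended with scan day or slide as a block, at log2 fold changes of -2.42 and -2.31 and a limma adjusted p of 0.0601 and 0.0898.

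By gene list, 4 of the 33 lists fixed before the data were examined passed the test in UIP vs control (limma's camera with an estimated correlation between genes). Of 19 matrix metalloproteinases, 9 rose, none fell and 10 did not pass, with 9 also passing when adjusted over the list alone. MMP10 and MMP11 rose by 3.48 and 2.79. The list had an adjusted p of 0.0352. The study's title names MMP1 and MMP7, so this list is not independent evidence of its direction. Of 34 genes of collagens and fibrotic matrix, 21 rose and none fell (24 adjusted over the list alone), with an adjusted p of 0.0352. COL1A1, SFRP2 and COL10A1 rose by 2.76, 2.71 and 2.61. Of 10 genes of the insulin-like growth factor axis, 4 rose (5 adjusted over the list alone), with an adjusted p of 0.0354. IGF1, IGFBP5 and IGFBP2 rose by 2.10, 1.59 and 1.31. Of 16 alveolar type 1 cell genes, 12 fell and 1 rose (14 fell and 1 rose adjusted over the list alone), with an adjusted p of 0.0352. AGER, a receptor abundant on type 1 cells, and NCKAP5 had log2 fold changes of -2.27 and -1.91. Camera used only genes with a value on every array, so its p rests on 18 of the metalloproteinases and 13 of the type 1 cell genes, and below on 16 of the type 2 cell, 22 of the basal and squamous, 23 of the endothelium and 20 of the B and plasma cell genes. Mean log2 fold changes of these lists with scan day as a block were 1.28, 1.32, 0.81 and -1.56, in the order given. There, only the type 1 list stayed past the threshold, with an adjusted p of 0.0259 against 0.0616 for each of the others. With slide as a block the mean log2 fold changes were 1.26, 1.27, 0.78 and -1.49, and the metalloproteinase and type 1 lists stayed past it, with an adjusted p of 0.0475 each. A further list newly passed with slide as a block, which made 3 of 33. Within scan days 2, 3 and 4 the means were 2.03, 1.01 and 1.09 for the metalloproteinases and 1.40, 1.04 and 1.47 for the fibrotic matrix. They were 0.95, 0.66 and 0.84 for the growth factor axis and -2.59, -1.63 and -1.04 for the type 1 cells, and none of the 4 lists passed within a single day. Without control replicate 5 none of the 4 lists passed, each at an adjusted p of 0.0503. Their mean log2 fold changes were then 1.21, 1.30, 0.79 and -1.34, against 1.25, 1.32, 0.81 and -1.38 with all arrays. None passed either with each array centred on its median or with the mean of a gene's probes, where 0 of 33 lists were called.

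The following lists did not pass as lists in the fit without a block. Of 24 endothelium genes, 14 fell and 1 rose (19 fell and 2 rose adjusted over the list alone), among them BTNL9 with a log2 fold change of -2.01, at an adjusted p of 0.0772 with an estimated correlation. Of 35 cell cycle genes, 15 rose (24 adjusted over the list alone), among them RRM2 and TOP2A by 1.58 and 1.29, at an adjusted p of 0.244 with an estimated correlation. KIF20A and CENPA rose as well, but turned to -0.080 and -0.36 with normexp and 75th percentile scaling. Of 23 basal and squamous epithelium genes, 8 rose (18 adjusted over the list alone), among them KRT5 and KRT14 by 3.57 and 3.03, at an adjusted p of 0.139 with an estimated correlation. Markers of multiciliated airway cells had a median log2 fold change of 1.23, and none of 27 passed, with an estimated correlation between genes of 0.858. Its members with the highest mean level, TPPP3 and CAPS, had log2 fold changes of 0.44 and 1.15, and TPPP3 was at -0.26 within scan day 3. Of 21 B and plasma cell genes, 7 rose (11 rose and 1 fell adjusted over the list alone), among them CXCL13, a B cell chemoattractant, by 2.52, and FCRL5 by 1.84, at an adjusted p of 0.374 with an estimated correlation. Over all 16070 genes tested, 1460 passed, 789 higher and 671 lower in UIP, and 706 of them changed at least 2-fold. The count was 1647 with scan day as a block and 1757 with slide. Within scan day 2 the count was 333 and within scan day 4 it was 380, while within scan day 3 limma called 0, with 1323 at an unadjusted p under 0.05. Chance alone would be expected to put a share of 0.05 of the 16070 genes there. Normexp background correction with 75th percentile scaling moved the share of higher genes from 54.0% to 40.7%, with 939 genes called and a median log2 fold change over all genes of -0.116, against 0.00263 as reported.

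**Figure D2:**
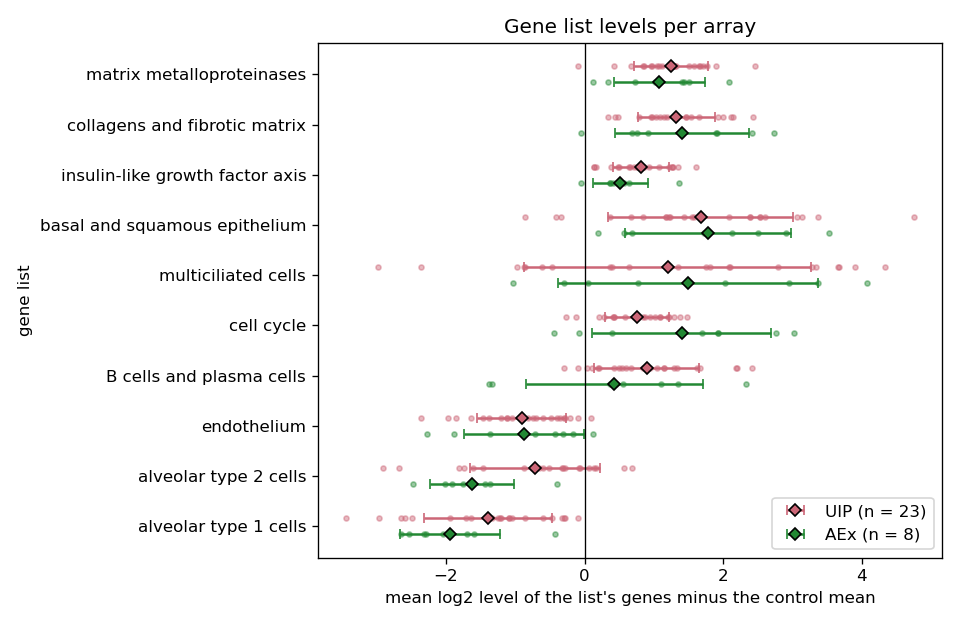
Mean log2 level of the genes of 10 lists on each UIP and AEx array, minus the mean of the control group. Small points are arrays and diamonds with bars are the mean ± SD; the type 1 cell list lies lowest, at a mean of -1.39 in UIP and -1.94 in AEx.

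The second comparison set AEx lung against control lung. Many type 2 and type 1 cell genes were lower in AEx and many cell cycle genes were higher, although none of the 33 lists passed as a list with an estimated correlation. Of 17 alveolar type 2 cell genes, 14 fell and none rose (14 adjusted over the list alone). HHIP, the surfactant protein genes SFTPD and SFTPA1, and LAMP3 had log2 fold changes of -3.17, -2.78, -2.56 and -2.61. Of 16 type 1 cell genes, 14 fell (14 adjusted over the list alone), among them ITLN2 with -5.15 ± 0.91 (SE), RTKN2 with -3.89 and AGER with -2.96. Of 35 cell cycle genes, 27 rose and none fell (32 adjusted over the list alone). RRM2, a subunit of ribonucleotide reductase, and TOP2A, a topoisomerase, rose by 2.27 and 2.12, with 6 and 8 of 8 AEx arrays above the control mean. The rise was not uniform, since the mean of the cell cycle list relative to control ran from -0.44 to 3.03 over the AEx arrays. CCNA2, which encodes cyclin A2, rose by 1.80 ± 0.26 (SE) with a limma adjusted p of 1.74e-05, and 8 of 8 AEx arrays lay above the control mean. Of 34 fibrotic matrix genes, 19 rose (23 adjusted over the list alone), led by COMP with 4.30 ± 0.47 and CTHRC1 with 3.04. Of 23 basal and squamous genes, 10 rose and 2 fell (15 rose and 2 fell adjusted over the list alone). SERPINB3 and SERPINB4, near-identical neighbours whose probes may not tell them apart, rose by 5.59 and 5.23. Of 25 acute inflammatory mediators, 2 rose and 4 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.46 and an adjusted p of 0.804 with an estimated correlation. Its direction was not the same on both scan days, since the mean of the list acute inflammatory mediators, AEx vs control, was 1.92 within scan day 2 and -1.75 within scan day 3, at an adjusted p of 0.3 and 0.325. Those that rose were SAA1 and SAA2, near-identical acute-phase proteins, by 3.92 and 3.73, while the chemokine genes CXCL2 and CXCL3 had log2 fold changes of -1.89 and -1.83, with 7 of 8 AEx arrays below the control mean for each. The call of CXCL3 ended with scan day as a block (log2 fold change of -1.89, adjusted p of 0.0641) and those of CXCL2 and CXCL3 with slide (-1.61 and -1.62, adjusted p of 0.0685 and 0.131). Markers of multiciliated airway cells had a median log2 fold change of 1.55, and none of 27 passed.

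MMP1 was higher in AEx than in control, with a level of 1.54 ± 1.59 (SD, n = 8) and a log2 fold change of 4.12 ± 0.94 (SE) at a limma adjusted p of 0.00262. MMP7 was higher as well, at 2.44 ± 2.20 (SD, n = 8) and a log2 fold change of 2.04 ± 0.70 with a limma adjusted p of 0.0483. Two-sided exact permutation tests gave p = 0.00104 for MMP1 and 0.026 for MMP7. The log2 fold change of MMP1 AEx vs control was 3.65 with scan day as a block, 3.94 with slide, 6.85 within scan day 2 and 1.45 within scan day 3, where its limma adjusted p was 0.684. For MMP7 AEx vs control the values were 1.83, 2.10, 3.25 and 1.05, and the call ended with scan day as a block, at a limma adjusted p of 0.124, and within both days, at 0.179 and 0.741. With normexp background correction and 75th percentile scaling the values were 2.88 for MMP1 and 1.88 for MMP7, whose call ended there at a limma adjusted p of 0.107. DEFA4, a neutrophil alpha-defensin, had a log2 fold change of 1.94 ± 1.08 with a limma adjusted p of 0.278. FOSB, CRTAC1, LGALS2, CD1C and HSD17B6 had log2 fold changes of -4.02, -3.82, -3.73, -3.37 and -3.30. BPIFA1, BPIFB1 and MSMB, secretory proteins, rose by 4.72, 4.00 and 4.36.

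In all, 1736 of 16070 genes passed, 840 higher and 896 lower in AEx, and 1082 changed at least 2-fold. The count was 1158 with scan day as a block, 1187 with slide, within scan day 2 alone 556 and within scan day 3 alone 0. On scan day 3, 1798 had an unadjusted p under 0.05, where chance alone would be expected to put a share of 0.05 of the 16070 genes. Of the 95 genes that the naming rule took past the threshold, 18 lost the call with scan day as a block and 19 with slide. Among them with either block were BPIFB1 (log2 fold changes of 3.65 and 3.94, limma adjusted p of 0.12 and 0.0628) and MSMB (3.98 and 4.26, limma adjusted p of 0.107 and 0.0829). No list passed camera with an estimated correlation, and 5 had an unadjusted p under 0.05. The adjusted p was 0.0825 for type 1 cells, 0.124 for type 2 cells, cell cycle and fibrotic matrix alike, and 0.251 for basal and squamous epithelium. With a preset correlation of 0.01, 18 lists passed, with limma's fry 15 did, and without AEx replicate 7 camera called 4. All controls stood at position 4 of a slide and no AEx or UIP array did, so position cannot be separated from either comparison with control.

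The third comparison set AEx lung against UIP lung. CD1C, CD1A, CCL17, FCER1A and CCR7 were lower in AEx than in UIP, and the cyclin gene CCNA2 and the histone genes H2AC19 and H3C10 were higher, but no gene stayed past the threshold once scan day or slide was a block. CD1C, a lipid antigen-presenting molecule of dendritic cells, had a level of -5.11 ± 1.80 (SD, n = 8) in AEx and -1.97 ± 1.43 (SD, n = 23) in UIP, a log2 fold change of -3.14 ± 0.55 (SE) with a limma adjusted p of 0.0027. CD1A, the chemokine CCL17, the IgE receptor chain FCER1A and the chemokine receptor CCR7 had log2 fold changes of -2.89, -2.68, -2.44 and -2.27. For CD1C, CD1A, CCL17 and CCR7, 8 of 8 AEx arrays lay below the UIP mean, and for FCER1A 7 of 8 did. FCER1A is also a mast cell gene, and of 11 mast cell genes 1 fell, this one (6 adjusted over the list alone). The list mast cells, AEx vs UIP, had a median log2 fold change of -1.29, an adjusted p of 0.193 with an estimated correlation and of 0.0352 with fry, and a mean of -1.16 that was -1.06 with scan day as a block and -1.11 with slide. WIF1, an inhibitor of WNT signalling, DDC, RHEX and SHISA2 had log2 fold changes of -2.17, -2.13, -2.02 and -1.99, and SHISA2 and KLHDC8A turned to 0.048 and 0.12 with normexp and 75th percentile scaling. KLHDC8A was not well above background on any AEx array, and its level was at least 1.72-fold lower there.

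OLFM4, a glycoprotein of neutrophils and epithelium, was higher in AEx by a log2 fold change of 3.92 ± 0.89 (SE) with a limma adjusted p of 0.0374. CCNA2 rose by 1.20 ± 0.25 with a limma adjusted p of 0.0139, and 8 of 8 AEx arrays lay above the UIP mean. Of 35 cell cycle genes it was the only 1 past the threshold (1 adjusted over the list alone). That list did not pass, with a median log2 fold change of 0.69 and an adjusted p of 0.438 (camera with an estimated correlation). The histone genes H2AC19 and H3C10 rose by 1.31 and 1.15, where the probe of H2AC19 may also detect its copy H2AC18. HSPA1A, a heat shock chaperone whose probe may also detect HSPA1B, rose by 1.24. HDAC10, NPL, DNASE1L2 and TMOD2 rose by 1.33, 1.27, 1.20 and 1.17. The probe named for the small nucleolar RNA SNORD14E rose by 3.23. In hg18 it lies on chromosome 11 from 122433842 to 122433901, beside the HSPA8 probe at 122433484 to 122433543, so it may detect HSPA8 transcripts. The HSPA8 probe itself did not pass, however. Of 23 heat shock and chaperone genes, HSPA8 among them, 1 passed, HSPA1A (2 rose and 1 fell adjusted over the list alone). DEFA4 had a log2 fold change of 3.82 ± 1.01 with a limma adjusted p of 0.0716, and DEFA3 one of 3.99 ± 0.97 with a limma adjusted p of 0.0508. MMP1 did not differ detectably between AEx and UIP, with a log2 fold change of -0.47 ± 0.88, a limma adjusted p of 0.915 and a two-sided exact permutation p of 0.575. For MMP7 the values were -1.06 ± 0.65, 0.583 and 0.118. With scan day as a block the log2 fold changes of MMP1 and MMP7 were -1.09 and -1.28, with slide as a block -0.88 and -1.02, within scan day 2 -1.27 and -1.13, and within scan day 3 -1.61 and -2.02.

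**Figure D3:**
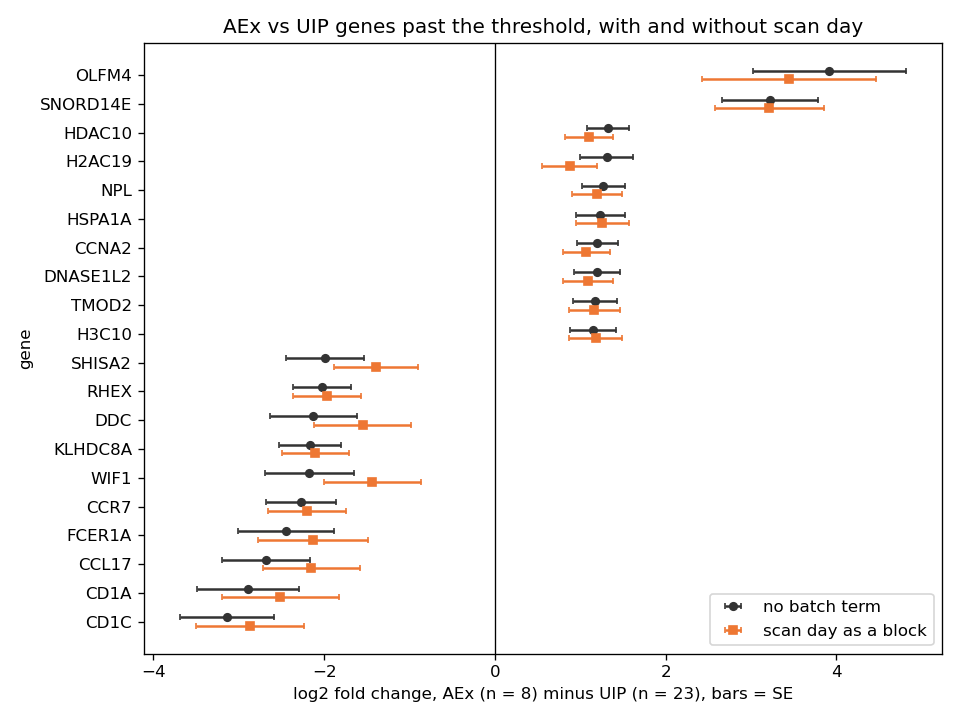
Log2 fold change of AEx over UIP for the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with bars for the SE, fitted without a batch term (circles) and with scan day as a block (squares). OLFM4 is at 3.92 without the term and 3.44 with it, and CD1C at -3.14 and -2.86.

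Of 16070 genes, 45 passed, 18 higher and 27 lower in AEx, 37 of them with at least a 2-fold change, and 1815 had an unadjusted p under 0.05. Of the 33 lists the WNT pathway passed, at an adjusted p of 0.00813 and with a mean log2 fold change of -0.52. Only WIF1 of its 30 genes fell past the threshold (2 adjusted over the list alone). The list mixes WNT ligands and receptors with inhibitors such as WIF1, so its lower mean gives no direction of WNT signalling. Once scan day was a block limma called no gene and camera no list, and neither did with slide as a block or within scan day 2 or 3. Scan day 4 held 14 of the 23 UIP arrays and no AEx array, so either block leaves fewer UIP arrays to compare directly with AEx. The loss of the calls can thus come from lower precision as well as from scan day or slide, and does not tell these apart. The genes at an unadjusted p under 0.05 numbered 967 with scan day, 1000 with slide, 940 within day 2 and 129 within day 3. With no true difference a share of 0.05 of the 16070 genes would be expected there. These counts by themselves thus do not show a remaining difference. The mean log2 fold change of the WNT list was -0.40 with scan day, -0.42 with slide, -0.36 within day 2 and -0.20 within day 3. The directions of all 22 genes named by the rule for this comparison were the same with either block. Of these, 20 were named because they passed the threshold in the same arrays, so their shared direction is little evidence of a difference. All AEx arrays stood at position 1 of a slide, against 5 of 23 UIP arrays. The share of higher genes moved from 40% to 26.3% with median centring, which called 19 genes, and to 65.1% with normexp and quantile normalization, which called 63. It was 50% of 4 genes with normexp and 75th percentile scaling, where the median log2 fold change over all genes was 0.149, against 0.0108 as reported. Leaving out 1 array at a time gave 9 to 160 genes. The count was 160 without UIP replicate 1, 92 without UIP replicate 2, 85 without UIP replicate 23, 96 without AEx replicate 6 and 131 without AEx replicate 8. It was 23, 16 and 29 without UIP replicates 3, 5 and 19, and 19, 9, 19, 13, 27 and 29 without AEx replicates 1, 2, 3, 4, 5 and 7.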

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

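The tests of scan day and of other splits of the arrays were chosen after the results were seen, while the tests of slide position, of other dendritic cell markers, of the cell cycle score and of the multiciliated cell score were written down before their results were seen.

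Among the 8 AEx arrays, 1 array stood apart from the others for 8 of 110 genes examined and 2 of 33 list means, by a gap to its neighbour that, as a share of the whole range, exceeds Dixon's 95% critical value, which chance passes in about 1 of 20 groups. The share was 0.594 for CD163, 0.588 for DNASE1L2, 0.564 for HDAC10, 0.601 for LGALS2, 0.53 for MMP3 and 0.625 for WNT7A, each at the low end. It was 0.6 for ITLN2 and 0.605 for RTKN2 at the high end. For the mean level of the alveolar type 1 cell list it was 0.53, and for hypoxia and glycolysis 0.595, both at the high end.

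CD1C, CD1A, CCL17, FCER1A and CCR7 were lower in AEx than in UIP, with a mean difference of -2.69 ± 0.47 (SE). They were picked as the largest falls past the threshold in these same arrays. The size and SE of their mean difference, also with scan day as a term or within a day, are thus not independent evidence of a difference. Among UIP arrays of scan day 4, 5 at position 1 differed from 9 at positions 2 and 3 by -0.25 ± 0.35. This argues against a slide position effect of the whole size on that day. No AEx array was scanned then, and no UIP array of scan days 2 and 3 stood at position 1, so position stays open there. With scan day as a term the AEx minus UIP difference was -1.87 ± 0.52. It was -2.49 ± 0.38 within scan day 2 and -1.26 ± 1.29 within scan day 3, so a part due to scan day stays open. Fewer dendritic cells may account for the pattern, since 10 other dendritic cell markers differed by -0.85 ± 0.22, but with scan day as a term they differed by -0.51 ± 0.26, which is within 2 SE of no difference, and 11 mast cell genes, FCER1A among them, had a mean log2 fold change of -1.16 with an adjusted p of 0.193. CCR7 is also in the list of T and natural killer cell genes, where it alone of 27 fell past the threshold. That list had a median log2 fold change of -0.34 and an adjusted p of 0.471 with an estimated correlation. Fewer mast or T cells, the exacerbation itself and its treatment, which the labels do not give, stay open and were not tested.

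Of 58 replication-dependent histone genes, the mean was higher in AEx than in UIP by 0.53 ± 0.15 (SE). With scan day as a term it was 0.24 ± 0.17, and among UIP arrays of scan day 4 position 1 differed from the others by 0.0040 ± 0.18, which is too imprecise to decide. With the cell cycle score as a term the difference was 0.52 ± 0.17, while that score itself was higher by 0.65 ± 0.31. The values for scan day and position are too imprecise to say how much either contributed. The cell cycle score as a term left the difference nearly unchanged, which argues against that score accounting for all of it. The SE there is that of the remaining difference and not of a contribution, so a part from more dividing cells stays open. Scan day, position and more dividing cells could each contribute, and they cannot be told apart here.

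Basal and squamous epithelium genes were higher in UIP than in control by a mean of 1.67 ± 0.38 (SE). Scan day as the whole cause was argued against by the value with scan day as a term, 1.75 ± 0.39, with 3.73, 0.90 and 1.25 within scan days 2, 3 and 4. More airway epithelium in the piece of tissue could account for a part, since with the multiciliated cell score as a term the difference was 1.12 ± 0.29, and that score was higher by 1.20 ± 0.60. Disease and site of sampling stay open and were not tested.

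Other splits of the same arrays into groups of the same sizes were drawn, 100 with the real one. For genes in UIP vs control, 2 splits gave as many as the real 1460, the real one included, and the other called 3422, for which no cause was identified. For the 2-fold count and the list count of that comparison it was 1 split, with 706 genes against at most 272 and 4 lists against at most 1. In AEx vs control 1 split gave as many genes as the real 1736, with at most 96 in another, and 1 gave as many at 2-fold as the real 1082, with at most 83. In AEx vs UIP 2 splits gave as many genes as the real 45, with at most 105, and 2 gave as many at 2-fold as the real 37, with at most 98. For these counts the share of splits that reached the real value was under 0.05. With 100 splits this makes chance unlikely but does not exclude it. The splits ignored scan day, so they say nothing about it. The counts with scan day as a block were 1647 genes in UIP vs control, 1158 in AEx vs control and 0 in AEx vs UIP. For the list count of AEx vs UIP, 12 splits gave at least the real 1 (at most 4), so that count gives no evidence against chance. For lists in AEx vs control the real count was 0, which every split must reach, so the splits test nothing there (at most 1 in another).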

How the results depend on the processing

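Chosen after the data were seen were the fits within a scan day, over scan days 2 and 3 alone, with unnamed probes and without control replicate 1 and UIP replicate 15, while the other alternatives were fixed before the data were examined. Counts were called unchanged when within 1.5 times the reported value. Over all alternatives and left-out arrays, 5122 of 5781 values of named genes in UIP vs control kept direction and side of the threshold, 653 lost the call and 6 changed sign. In AEx vs control it was 3706 of 4181, with 473 and 2, and in AEx vs UIP 820 of 1131, with 291 and 2 and a further 18 newly past it. Most of these values come from fits that leave out 1 array and so share nearly all arrays with the reported fit. Those fits kept 3449 of 3686, 2056 of 2208 and 537 of 682 values, in the same order, so the totals overstate how stable the calls are. For lists 1904 of 2043, 1442 of 1515 and 1599 of 1779 values kept both, 72, 31 and 157 changed direction, 42, 0 and 7 lost the call and 25, 42 and 16 newly passed. As no list passed in AEx vs control, a list kept there is one that failed in both fits. With camera the direction of a list is that of its test against all other genes, and with fry against no change. A list can therefore change direction while its mean log2 fold change keeps its sign. MMP1 has no value for probes well above background on every array, as its probe is then left out. Signal over background limits dim probes, with 59.5% to 85.4% of probes well above it. Except where fewer samples or genes were fitted, the cause was not tested.

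With each array centred on its median the number of genes was 19 in AEx vs UIP, and the number at 2-fold was 19 in AEx vs UIP, and the number of lists was 0 in UIP vs control, 0 in AEx vs UIP. With normexp and the 75th percentile the number of genes was 939 in UIP vs control, 522 in AEx vs control, 4 in AEx vs UIP, and the number at 2-fold was 308 in UIP vs control, 332 in AEx vs control, 4 in AEx vs UIP, and the number of lists was 2 in UIP vs control, 3 in AEx vs control, 0 in AEx vs UIP. With normexp and quantile normalization the number at 2-fold was 315 in UIP vs control, 556 in AEx vs control, 16 in AEx vs UIP. For probes well above background on every array, which leaves fewer genes, the number of genes was 900 in UIP vs control, 1156 in AEx vs control, 18 in AEx vs UIP, and the number at 2-fold was 325 in UIP vs control, 597 in AEx vs control, 11 in AEx vs UIP. Averaging the probes of a gene the number of lists was 0 in UIP vs control. Taking the probe with the largest variance the number of genes was 78 in AEx vs UIP, and the number at 2-fold was 61 in AEx vs UIP. Including unnamed probes the number of genes was 73 in AEx vs UIP, and the number at 2-fold was 61 in AEx vs UIP. Fitting only the groups compared the number of lists was 1 in AEx vs control. Using array weights the number of genes was 289 in AEx vs UIP, and the number at 2-fold was 143 in AEx vs UIP. With scan day as a block the number of genes was 0 in AEx vs UIP, and the number at 2-fold was 0 in AEx vs UIP, and the number of lists was 1 in UIP vs control, 0 in AEx vs UIP. With slide as a block the number of genes was 0 in AEx vs UIP, and the number at 2-fold was 0 in AEx vs UIP, and the number of lists was 0 in AEx vs UIP. With camera's preset correlation the number of lists was 18 in UIP vs control, 18 in AEx vs control, 15 in AEx vs UIP. Using fry the number of lists was 12 in UIP vs control, 15 in AEx vs control, 2 in AEx vs UIP. Within scan day 2 the number of genes was 333 in UIP vs control, 556 in AEx vs control, 0 in AEx vs UIP, and the number at 2-fold was 333 in UIP vs control, 556 in AEx vs control, 0 in AEx vs UIP, and the number of lists was 0 in UIP vs control, 0 in AEx vs UIP, and the log2 fold change was 4.37 for MMP7 UIP vs control. Within scan day 3 the number of genes was 0 in UIP vs control, 0 in AEx vs control, 0 in AEx vs UIP, and the number at 2-fold was 0 in UIP vs control, 0 in AEx vs control, 0 in AEx vs UIP, and the number of lists was 0 in UIP vs control, 0 in AEx vs UIP, and the log2 fold change was 3.07 for MMP1 UIP vs control, 3.07 for MMP7 UIP vs control. Within scan day 4 the number of genes was 380 in UIP vs control, and the number at 2-fold was 314 in UIP vs control, and the number of lists was 0 in UIP vs control. Over scan days 2 and 3 alone the number of genes was 396 in UIP vs control, 773 in AEx vs control, 0 in AEx vs UIP, and the number at 2-fold was 378 in UIP vs control, 649 in AEx vs control, 0 in AEx vs UIP, and the number of lists was 0 in UIP vs control, 0 in AEx vs UIP. Leaving out the pair of arrays that correlated least the number of genes was 106 in AEx vs UIP, and the number at 2-fold was 66 in AEx vs UIP.

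The replicate numbers do not pair the samples, since same-number pairs correlated over 0.1 in 2 of 15, 4 of 8 and 2 of 8 cases, and 0, 1 and 0 samples correlated best with their own number. With the replicate number as a block the number of genes was 634 in UIP vs control, 1017 in AEx vs control, 12 in AEx vs UIP, and the number of genes at 2-fold was 445 in UIP vs control, 10 in AEx vs UIP, and the number of lists was 0 in UIP vs control. With the replicate number as a block, values were, for UIP vs control metalloproteinase inhibitors 0.27, adipocytes 0.058 and for AEx vs UIP matrix metalloproteinases -0.037, collagens and fibrotic matrix -0.076, TGF-beta axis 0.012, airway secretory cells 0.19, submucosal gland 0.14, basal and squamous epithelium 0.25, acute inflammatory mediators 0.10, ribosomal proteins -0.017.

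Leaving out 1 array at a time gave 1257 to 1786 genes in UIP vs control, 1343 to 1938 in AEx vs control and 9 to 160 in AEx vs UIP. At 2-fold it gave 624 to 870, 895 to 1227 and 9 to 103. The lists numbered 0 to 5 in UIP vs control, with 0 without control replicate 5. They numbered 0 to 4 in AEx vs control, with 4 without AEx replicate 7 and 1 without control replicate 6, and 1 to 2 in AEx vs UIP, with 2 without AEx replicate 6. MMP1 ranged from 4.27 to 4.87 in UIP vs control and from -0.77 to -0.16 in AEx vs UIP, and MMP7 from 2.83 to 3.27 and from -1.51 to -0.59. The lists whose direction changed for some left-out array, none of them past the threshold, had mean log2 fold changes of hypoxia and glycolysis, UIP vs control -0.059 to 0.065, adipocytes, UIP vs control -0.021 to 0.19, cartilage, AEx vs control 0.047 to 0.14, alveolar macrophages, UIP vs control -0.046 to 0.13, TGF-beta axis, UIP vs control 0.035 to 0.11, endothelium, AEx vs UIP -0.11 to 0.23, TGF-beta axis, AEx vs UIP -0.030 to 0.091, airway secretory cells, AEx vs UIP -0.093 to 0.31, acute inflammatory mediators, AEx vs UIP -0.30 to 0.35, smooth muscle and myofibroblast, AEx vs UIP -0.13 to -0.0094, basal and squamous epithelium, AEx vs UIP -0.14 to 0.34, mast cells, UIP vs control -0.15 to 0.064, submucosal gland, AEx vs UIP -0.16 to 0.092, collagens and fibrotic matrix, AEx vs UIP -0.10 to 0.29, alpha-defensins and granule proteins, AEx vs control 0.0039 to 0.94, erythroid cells, AEx vs control -0.22 to 0.64, TGF-beta axis, AEx vs control 0.052 to 0.17, multiciliated cells, AEx vs UIP -0.077 to 0.65.

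Genes and lists that changed direction are given with their log2 fold change or mean log2 fold change. Quantile normalization, values were, for UIP vs control metalloproteinase inhibitors 0.34, ribosomal proteins 0.052 and for AEx vs control ribosomal proteins 0.055 and for AEx vs UIP smooth muscle and myofibroblast -0.026, airway secretory cells 0.13, acute inflammatory mediators 0.087. Cyclic loess, values were, for UIP vs control adipocytes 0.13 and for AEx vs UIP airway secretory cells 0.10, endothelium 0.028. With each array centred on its median, values were, for UIP vs control adipocytes 0.053 and for AEx vs UIP airway secretory cells 0.056, basal and squamous epithelium 0.076, endothelium -0.0033. With normexp and the 75th percentile, values were, for UIP vs control KIF20A -0.080, CENPA -0.36, CA9 -0.24, metalloproteinase inhibitors 0.16, mast cells -0.066, hypoxia and glycolysis -0.023, cartilage -0.20, ribosomal proteins -0.013 and for AEx vs control TGF-beta axis -0.0084, cartilage 0.15 and for AEx vs UIP KLHDC8A 0.12, SHISA2 0.048, collagens and fibrotic matrix 0.015, TGF-beta axis 0.044, submucosal gland 0.29, acute inflammatory mediators 0.050, cartilage 0.35, ribosomal proteins -0.035, p53 and senescence 0.15. With normexp and quantile normalization, values were, for UIP vs control metalloproteinase inhibitors 0.17, ribosomal proteins 0.047 and for AEx vs control ribosomal proteins 0.045 and for AEx vs UIP TGF-beta axis 0.026. No filter on dim probes, values were, for UIP vs control mast cells -0.014, adipocytes 0.071 and for AEx vs UIP TGF-beta axis 0.033, submucosal gland 0.092, acute inflammatory mediators 0.11. For probes well above background on every array, values were, for UIP vs control TGF-beta axis -0.095 and for AEx vs control TGF-beta axis -0.034, submucosal gland 0.094 and for AEx vs UIP acute inflammatory mediators -0.026. Averaging the probes of a gene, values were, for UIP vs control adipocytes 0.063 and for AEx vs UIP TGF-beta axis -0.0047, airway secretory cells 0.14. Taking the probe with the largest variance, values were, for UIP vs control hypoxia and glycolysis 0.022, adipocytes 0.064 and for AEx vs UIP TGF-beta axis -0.032, airway secretory cells 0.21, endothelium 0.0087. Including unnamed probes, values were, for UIP vs control adipocytes 0.070 and for AEx vs control cartilage 0.085 and for AEx vs UIP airway secretory cells 0.091, basal and squamous epithelium 0.11, endothelium 0.032. Fitting only the groups compared, values were, for AEx vs control cartilage 0.085 and for AEx vs UIP acute inflammatory mediators 0.11. Using array weights, values were, for UIP vs control mast cells 0.13, adipocytes 0.085 and for AEx vs control cartilage 0.11 and for AEx vs UIP matrix metalloproteinases 0.0021, smooth muscle and myofibroblast -0.021, TGF-beta axis -0.0061, airway secretory cells 0.25, submucosal gland 0.14, basal and squamous epithelium 0.37. With scan day as a block, values were, for UIP vs control adipocytes 0.096 and for AEx vs control submucosal gland 0.17 and for AEx vs UIP smooth muscle and myofibroblast -0.021, multiciliated cells -0.43, endothelium 0.20, acute inflammatory mediators -0.059. With slide as a block, values were, for UIP vs control TGF-beta axis 0.034, adipocytes 0.11 and for AEx vs UIP smooth muscle and myofibroblast -0.047, multiciliated cells -0.44, endothelium 0.13. Using fry, values were, for UIP vs control adipocytes 0.070 and for AEx vs control cartilage 0.085. Within scan day 2, values were, for UIP vs control BMP4 -0.0026, metalloproteinase inhibitors 0.56, TGF-beta axis -0.13, alveolar macrophages -0.85, neutrophils and monocytes 0.12, acute inflammatory mediators 1.31, immediate early genes 0.18, hypoxia and glycolysis 0.17, adipocytes 0.35, ribosomal proteins 0.094 and for AEx vs control GADD45B 0.18, acute inflammatory mediators 1.92, cartilage 0.23, ribosomal proteins 0.12 and for AEx vs UIP multiciliated cells -1.90, alveolar type 1 cells -0.019, endothelium 0.50, T cells and NK cells 0.23, fibrosis-associated macrophages 0.42. Within scan day 3, values were, for UIP vs control CNN1 -0.26, TPPP3 -0.26, metalloproteinase inhibitors 0.29, TGF-beta axis 0.0079, WNT pathway -0.27, alveolar macrophages -0.11, heat shock and chaperones -0.35, cartilage -0.16 and for AEx vs control CCL7 -1.31, TGF-beta axis -0.045, B cells and plasma cells -0.37, fibrosis-associated macrophages -0.24, neutrophils and monocytes -0.39, heat shock and chaperones 0.0037, hypoxia and glycolysis -0.40 and for AEx vs UIP collagens and fibrotic matrix -0.54, smooth muscle and myofibroblast 0.12, airway secretory cells 0.098, submucosal gland 0.12, alveolar type 2 cells 0.31, alveolar type 1 cells 0.37, endothelium 0.039, neutrophils and monocytes 0.053, acute inflammatory mediators -1.18, interferon response 0.43, hypoxia and glycolysis -0.31, p53 and senescence -0.14. Within scan day 4, values were, for UIP vs control submucosal gland 0.020, T cells and NK cells 0.0048, mast cells 0.72, hypoxia and glycolysis 0.041, adipocytes 0.40. Over scan days 2 and 3 alone, values were, for UIP vs control TGF-beta axis -0.068, WNT pathway -0.096, alveolar macrophages -0.46, acute inflammatory mediators 0.25, heat shock and chaperones -0.076 and for AEx vs UIP multiciliated cells -0.76, alveolar type 1 cells 0.19, endothelium 0.27, acute inflammatory mediators -0.29, interferon response 0.035. Leaving out the pair of arrays that correlated least, values were, for UIP vs control mast cells 0.081, hypoxia and glycolysis 0.043, adipocytes 0.077 and for AEx vs control cartilage 0.10 and for AEx vs UIP smooth muscle and myofibroblast -0.022, TGF-beta axis 0.0044, airway secretory cells 0.19, submucosal gland 0.092, basal and squamous epithelium 0.25.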

Other observations

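All tests in this part were chosen after the results were seen, and their adjusted p-values do not account for that choice.

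Natural killer cell receptors were lower in UIP than in control lung. Of 12 tested, 7 fell and none rose, with a median log2 fold change of -0.86 and an adjusted p of 0.0448 over the 12 tests of 4 families in 3 comparisons (limma's camera with an estimated correlation). Once scan day was a block the median was -0.88 and the adjusted p 0.0488, and with slide they were -0.92 and 0.121, so the call ended there. The genes past the threshold were CD160, KIR2DL4, KIR3DL1, KIR3DL2, KLRF1, NCR1 and SH2D1B. The KIR genes are close copies of each other, and their values are uncertain for that reason. In AEx vs control 2 of 12 fell, with an adjusted p of 0.0727. The list of T and natural killer cell genes fixed before the data were examined did not pass in UIP vs control. Of its 27 genes 4 fell and 1 rose, with a median log2 fold change of -0.19 and an adjusted p of 0.527 (camera with an estimated correlation). Of 12 genes of xenobiotic and aldehyde metabolism, 7 rose in UIP, with a median of 1.84 and an adjusted p of 0.0727, so the family did not pass. AKR1B10, an aldo-keto reductase, rose by 2.37, and GSTA1, GSTA2 and GSTA5 are near-identical copies.

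Of 58 replication-dependent histone genes (the family's p leaves out H3C4, which lacks a value on an array), 28 rose and 2 fell in AEx vs control, with an adjusted p of 0.0727 for the family, which did not pass. In AEx vs UIP 8 of 58 rose and none fell, with a median log2 fold change of 0.59 and an adjusted p of 0.0448. That call ended with scan day as a block, at a median of 0.35 and an adjusted p of 0.0991 with none of 58 past the threshold, and with slide, at 0.40 and 0.136. Histone genes are in part close copies of each other, and cross-detection by their probes was not checked. Among the 8 that rose in AEx vs UIP, H2BC6, H2BC7, H2BC9, H2BC13 and H2BC17 had log2 fold changes of 0.80 to 0.89. The numbers of histone genes past the threshold may thus not be numbers of separate genes. The histone family includes H2AC19 and H3C10, which were seen among the largest rises of AEx vs UIP before it was chosen. Its p is thus not independent evidence of their direction. None of 10 dendritic cell markers passed alone in AEx vs UIP, with XCR1 at 0.24 and BATF3 at -0.076, and their median was -0.77 with an adjusted p of 0.0203. The median was -0.53 with scan day as a block, at an adjusted p of 0.0488, and with slide -0.62 with 0.121, so the call ended there.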
